A study of Mus musculus with 6 samples.

How the data were processed

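Naive mouse CD4 T cells received anti-CD3e coated on the plate (10 µg/ml), anti-CD28 (1 µg/ml), IL-6 (20 ng/ml), TGFb1 (2.5 ng/ml) and IL-23 (10 ng/ml) for 48 h with DMSO or 250 µM 2DG, per the labels' protocols. Total RNA was extracted and sequenced on an Illumina HiSeq instrument, 3 libraries per group. Sample titles give the numbers 17, 42 and 43 in both groups, as replicates 1, 2 and 3, without saying what the numbers mark.

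The submitters' processing notes name TopHat2 2.1.0, Cufflinks 2.2.1.0, Cuffnorm 2.2.1.1 and Cuffdiff 2.2.1.3 and the mm10 build. Their settings, the gene annotation, the use of strand and the scaling method are not given in the sources used here. The authors deposited one table with an FPKM value (fragments per kilobase of transcript scaled by mapped fragments) per locus and library, per the file headers, with a locus number, 1 or more gene symbols and a status of OK (10052 loci) or NOTEST (13151 loci). The values had been scaled across libraries before deposit: their 75th percentiles lay between 10.9 and 11.6 FPKM, while their sums lay between 1469420 and 1958740. Small RNA genes held 70.6% to 76.7% of each sum, because FPKM divides by a short length. Since FPKM are estimates, the values of genes that share reads with near-identical copies, overlapping genes or pseudogenes are uncertain, and an exact 0 can be a failed estimate; Gapdh, which every cell uses, was listed at 0.135 to 1.12 FPKM. Of the loci, 266 name several genes, among them that of Foxp3, and 7832 were at 0 in every library.

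No count test was possible on FPKM values, so tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 10228 loci with a mean of at least 1 FPKM over the 6 libraries. A linear model with group as the only term was fitted with lmFit and eBayes with a trend, p-values were two-sided and adjusted by Benjamini-Hochberg, and the threshold was 0.05. The pseudocount of 1 means that log2 fold changes understate the change of low genes. Fold changes without log2 are ratios of mean FPKM. With 3 against 3 libraries an exact permutation test of a single gene cannot go below 0.1, so significance rests on the spread that limma pools across genes. A simulation held 10228 genes, 200 changed, over 5 draws, with independent normal noise for each gene at the spread that limma estimated. On it the same code recovered 41.5% of genes changed 1.5-fold, 75.5% at 2-fold and 91.5% at 4-fold, with 4.41% of calls false. The simulation held no correlation between genes, no shared batch and no error of FPKM estimates. Its rates may therefore be better than those of the real data. The largest share of tested loci with identical values in a pair of libraries was 0.479%, so no library was taken as a copy of another.

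Before the data were examined, the design, 36 gene lists, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members (30 of 36) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes are the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted genes, pseudogenes, small RNAs and immune receptor segments; up to 4 members of smallest p per list; and a fixed set in any case, which includes Il17a, Il17f, Foxp3, Il10, Csf2, Ifng, Il23r, Tbx21, Hk2, Ldha, Slc2a1, Txnip, Hif1a and Myc. Genes outside this rule are marked as named after their values were seen. Symbols were matched directly or through synonyms, and coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 denotes.

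Relative depth was read from the most frequent log2 ratio of low values (between 0.002 and 0.3 FPKM) to vehicle replicate 1. Only 13.3% to 24.6% of these ratios lay within 0.05 of it, so whole fragments could not be recovered and the estimates (1 and 0.413 and 0.603 for vehicle, 1.10 and 0.597 and 0.844 for 2DG replicates 1 to 3) are rough. Alternatives fixed at the same time were another pseudocount (0.1), no filter, a minimum mean of 5, quantile normalization, rescaling to an equal sum, the replicate block, eBayes without trend or with robust fitting, leaving out each library and a 1.5-fold minimum. Alternatives chosen after seeing the data leave out small RNA genes, equalize sums without them, keep loci of status OK, add a term for replicate 1 against the others, use replicates 2 and 3 only, add relative depth as a covariate, or remove trends with GC content and transcript length by loess (span 0.5). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.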

Results

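Naive mouse CD4 T cells were turned into Th17 cells, the helper T cell type that makes IL-17, over 48 h in culture with a Th17 cytokine mix. The cultures received either vehicle (DMSO) or 250 µM 2-deoxyglucose (2DG), a glucose analogue used to inhibit glycolysis. RNA was sequenced from 3 vehicle and 3 2DG libraries. The question the design poses is how the Th17 transcriptome differs between cultures with 2DG and with vehicle. Glycolysis itself was not measured in the values used, so changes with 2DG cannot be assigned to its inhibition. The deposited table gave an FPKM value for each of 23203 loci in each library, and 10228 loci with a mean of at least 1 FPKM were tested. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. Read counts were not among the values used, so absolute depth is unknown. The steps between low values gave only a rough relative depth, which ran from 0.413 in vehicle replicate 2 to 1.10 in 2DG replicate 1, with vehicle replicate 1 set to 1. Libraries of one group correlated with r between 0.982 and 0.989 over log2 values of loci that are not small RNA genes, and libraries of different groups with r between 0.969 and 0.982. The replicate 1 libraries of both groups stood apart in a few loci. Rn45s, the ribosomal RNA precursor, was listed at 12874 FPKM in vehicle and 7186 FPKM in 2DG, and at 0 in the other 4 libraries.

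With 2DG, 156 genes were higher and 122 were lower than with vehicle (limma, Benjamini-Hochberg adjusted p under 0.05). Cth, a gene of cysteine synthesis, 3 of 10 amino acid transporter genes and 5 of 24 ER chaperone genes rose, as did Il17a and several other Th17 genes, while Il24, Crem and part of the genes typical of regulatory T cells fell. Transcripts of glycolytic enzymes did not pass the test in either direction. All 278 called genes had groups that did not overlap, as had 2425 of the tested loci (23.7%, against 10% by chance for 3 against 3). At least a 1.5-fold change was reached by 131 of the higher and 96 of the lower genes. The counts depended on the libraries and on the processing. They were 86 and 60 without vehicle replicate 1, 60 and 25 without vehicle replicate 2, 83 and 56 without vehicle replicate 3, 52 and 29 without 2DG replicate 1, 53 and 26 without 2DG replicate 2, and 98 and 69 without 2DG replicate 3. With replicates 2 and 3 only they were 43 and 28. They were 104 and 80 with a term for replicate 1 against the others. They were 57 and 44 with the replicate block, a term for each replicate number that no label says pairs the samples. After rescaling to an equal sum they were 87 and 63, with no filter 100 and 65, with robust eBayes 247 and 199, after the GC and length correction 231 and 191, and without small RNA genes 265 and 224. Of 53 called genes among those named by rule, 16 kept their call without each library in turn.

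The 10 largest rises were those of Xcl1, Cib2, Cd5l, Tff1, Slc7a3, Tmem176b, Pltp, Stc2, Cth and Crtam. Xcl1, a chemokine gene (locus XLOC_001120, chromosome 1, 164931644 to 164935527, GRCm38), had the largest log2 fold change among these called genes with the pseudocount of 1, 3.03 ± 0.56 (SE, adjusted p = 0.041). With a pseudocount of 0.1 Tff1 (5.03) and Cib2 (4.01) lay above Xcl1 (3.71). Its call was kept without vehicle replicate 3 (adjusted p = 0.0086) and lost without any other single library (highest adjusted p = 0.13). Cib2, for a calcium-binding protein (XLOC_021742, chromosome 9, 54544794 to 54560218), was at 0.521 ± 0.149 FPKM with vehicle and 10.0 ± 2.84 FPKM with 2DG (SD, n = 3 each). Cd5l, a gene linked to lipid metabolism in Th17 cells (XLOC_012717, chromosome 3, 87357881 to 87371073), went from 4.71 ± 1.90 to 35.5 ± 2.56 FPKM, a log2 fold change of 2.72 ± 0.22 (SE, adjusted p = 0.0032). Crtam, for a surface receptor of activated lymphocytes, rose by 2.01 ± 0.12 on the log2 scale (SE, adjusted p = 0.0016). Tff1 was listed at 0 in vehicle replicates 1 and 2 and at 1.18 FPKM in vehicle replicate 3, against 8.39, 9.86 and 5.14 FPKM in the 2DG libraries. Cib2, Cd5l, Slc7a3, Pltp, Cth and Crtam kept their call without each library in turn, and Pltp lost it with replicates 2 and 3 only (adjusted p = 0.073). Stc2 lost it without vehicle replicate 2 (adjusted p = 0.054), and Tff1 lost it without vehicle replicate 2, 2DG replicate 1 or 2DG replicate 2 (highest adjusted p = 0.063). Tmem176b, a transmembrane protein gene, kept it without 2DG replicate 3 (adjusted p = 0.041) and lost it without any other single library (highest adjusted p = 0.14).

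The 10 largest falls were those of Il24, Plaur, Crem, Vps37b, Procr, Sdcbp2, Gja5, Ltb4r1, Il12rb2 and Dgat1. Il24, a cytokine gene of the IL-10 family (XLOC_000988, chromosome 1, 130882074 to 130887454), dropped from 13.9 ± 4.40 FPKM to 0.883 ± 0.539 FPKM (SD, n = 3 each), a log2 fold change of -2.98 ± 0.26 (SE, adjusted p = 0.0040). Plaur, the urokinase receptor gene (XLOC_017784, chromosome 7, 24462484 to 24475968), was between 4.55 and 16.3 FPKM in the vehicle libraries and between 0.372 and 0.405 FPKM in the 2DG libraries. Crem, a transcriptional regulator of the cAMP response (XLOC_009576, chromosome 18, 3266048 to 3337748), went from 112 ± 31.8 to 22.1 ± 9.92 FPKM, with an adjusted p of 0.016. The others fell by 1.80 to 1.94 on the log2 scale. Among them Dgat1, the gene of a triglyceride-synthesizing enzyme, went from 58.2 ± 16.6 to 15.9 ± 3.80 FPKM. Il12rb2, a subunit of the IL-12 receptor, was at 11.8 ± 6.35 and 2.45 ± 0.850 FPKM. Il24 and Gja5 kept their call without each library in turn. Without vehicle replicate 2 the adjusted p was above 0.05 for each of the other 8, and without 2DG replicate 2 for 7 of them, with Procr as the exception. Without 2DG replicate 1 the call was lost by Plaur, Procr, Sdcbp2, Ltb4r1, Il12rb2 and Dgat1, without vehicle replicate 3 and 2DG replicate 3 by Procr and Il12rb2, and without vehicle replicate 1 by Ltb4r1. Their highest adjusted p was 0.063 for Plaur and Crem, 0.057 for Vps37b, 0.079 for Procr, 0.063 for Sdcbp2, 0.086 for Ltb4r1, 0.14 for Il12rb2 and 0.066 for Dgat1.

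Several Th17 genes were higher with 2DG. Il17a, which encodes the cytokine that defines these cells (XLOC_000035, chromosome 1, 20730905 to 20734496), rose 2.59-fold, from 252 ± 16.1 to 651 ± 69.2 FPKM (SD, n = 3 each), with a log2 fold change of 1.36 ± 0.11 (SE, adjusted p = 0.0032 by limma). It kept its call without each library in turn (highest adjusted p = 0.021). Its neighbour Il17f (XLOC_000676, chromosome 1, 20777146 to 20790617) was at 1501 ± 136 and 1958 ± 306 FPKM, a difference that did not pass (adjusted p = 0.25). Of 24 tested members of the Th17 core list, 6 rose, 1 fell and 17 did not pass over all genes. In it 10 were higher and 2 lower adjusted over the list alone. Rora, a nuclear receptor gene, rose by 0.77 ± 0.10 on the log2 scale (SE, adjusted p = 0.016; 0.056 without 2DG replicate 1), and Ltb4r1, the leukotriene B4 receptor gene, was the member that fell. Ccr6, a chemokine receptor gene, and Runx1, a transcription factor gene, named after their values were seen, rose by 1.12 and 0.83 (adjusted p = 0.025 and 0.030). The list stood above the other genes with a median log2 fold change of 0.57 (camera adjusted p = 4.69e-06; adjusted p = 0.35 with an estimated correlation). Its medians were 0.83 in the replicate 1 libraries and 0.30 in replicates 2 and 3.

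The split of Th17 genes into pathogenic and regulatory modules showed no uniform shift. In the pathogenic module 1 of 15 tested members rose, Tbx21, and none fell, and adjusted over the list alone 2 were higher and 0 lower. The list did not pass (median 0.41, camera adjusted p = 0.25). The median was -0.05 in the replicate 1 libraries and 0.44 in replicates 2 and 3, where it passed when these were tested alone (adjusted p = 0.0095). It also passed after rescaling to an equal sum (median 0.63, adjusted p = 0.018). The median was 0.20 without vehicle replicate 3, 0.77 without 2DG replicate 1 and 0.67 with a minimum mean of 5 FPKM, and the list passed in none of these cases. Csf2, for GM-CSF, was at 1.93 ± 0.643 and 1.01 ± 0.115 FPKM (SD, n = 3 each; adjusted p = 0.20), Il23r at 5.82 ± 2.28 and 10.6 ± 6.17 FPKM (adjusted p = 0.42), Gzmb at 4.04 and 2.29 FPKM (adjusted p = 0.15) and Lgals3 at 21.5 and 45.9 FPKM (adjusted p = 0.076; 0.045 without vehicle replicate 2). Of the 9 tested members of the regulatory module, Cd5l rose, none fell, and 3 were higher and 0 lower adjusted over the list alone. Its members Il6st, Maf, Ahr, Cd5l and Il17f are also in the Th17 core list, so the results of these lists are not independent. The regulatory list was called higher (median 0.37, camera adjusted p = 0.020), but with an estimated correlation its adjusted p was 0.58. The call was lost without vehicle replicate 1 (adjusted p = 0.15) and without 2DG replicate 2 (adjusted p = 0.079). It was also lost with equal sums outside small RNA genes (adjusted p = 0.051) and with replicates 2 and 3 only (0.36), and without vehicle replicate 1 the median was 0.20. Its median was 0.73 in the replicate 1 libraries and 0.11 in replicates 2 and 3. Il10, for an anti-inflammatory cytokine, was at 24.1 ± 9.18 FPKM with vehicle and 12.0 ± 5.10 FPKM with 2DG, which did not pass (adjusted p = 0.20).

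**Figure D1:**
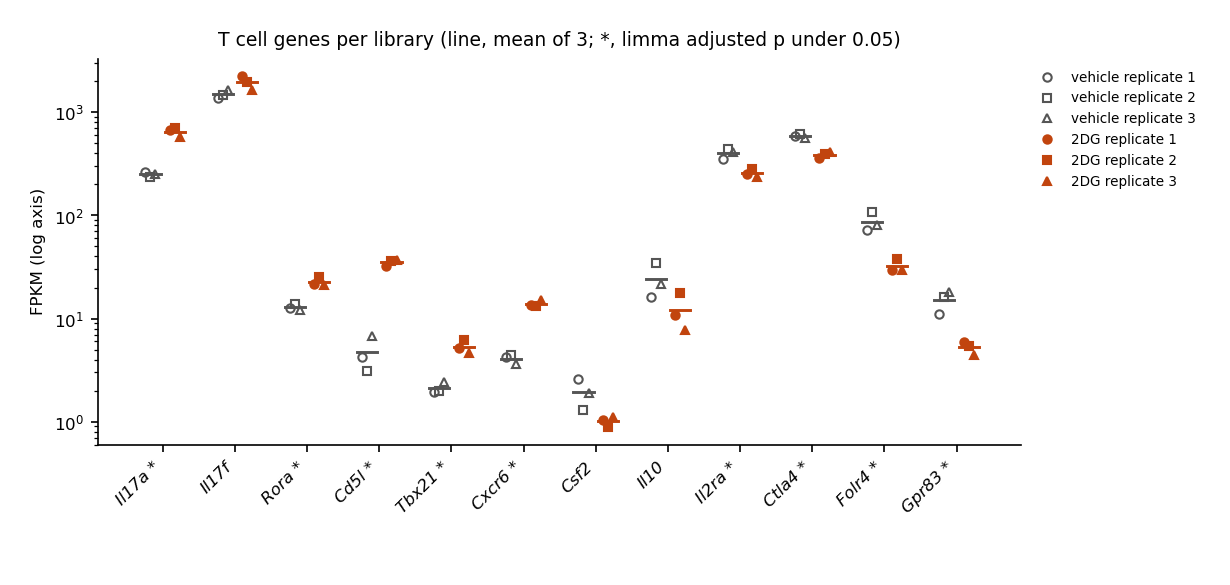
FPKM (log axis) of 12 T cell genes in each of the 3 vehicle libraries (open grey symbols) and 3 2DG libraries (filled orange symbols), with symbol shapes for replicates 1 to 3, lines for group means and an asterisk for a limma adjusted p under 0.05. Il17a lies near 252 FPKM with vehicle and 651 FPKM with 2DG, Cd5l and Cxcr6 also lie higher with 2DG, and Folr4 and Gpr83 lie lower.

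Genes of the Th1 programme moved in both directions. Cxcr6, a chemokine receptor gene, rose from 4.09 to 13.9 FPKM, by 1.55 ± 0.10 on the log2 scale (SE, adjusted p = 0.0016). Tbx21, which encodes T-bet, the Th1 lineage factor (XLOC_003771, chromosome 11, 97098071 to 97115331), rose from 2.13 ± 0.267 to 5.33 ± 0.793 FPKM (SD, n = 3 each; adjusted p = 0.016). It lost its call without vehicle replicate 2, 2DG replicate 1 or 2DG replicate 2 (highest adjusted p = 0.068). Il18rap, an IL-18 receptor subunit gene, also rose, by 1.22 on the log2 scale, and Il12rb2 fell. Il18rap lost its call without vehicle replicate 1, vehicle replicate 2, 2DG replicate 1 or 2DG replicate 2 (highest adjusted p = 0.12). Ifng stayed under the filter, at 0.618, 1.05 and 0.343 FPKM with vehicle and 0.190, 1.09 and 1.13 FPKM with 2DG. Of 12 tested members 4 rose, 1 fell and 7 did not pass, and 6 were higher and 3 lower adjusted over the list alone. The list was called higher (median 0.57, camera adjusted p = 0.023; adjusted p = 0.35 with an estimated correlation), with medians of 0.58 in the replicate 1 libraries and 0.33 in replicates 2 and 3. That call was lost without vehicle replicate 3 (adjusted p = 0.070) or 2DG replicate 3 (adjusted p = 0.058), and with a minimum mean of 5 FPKM the median was -0.40 (adjusted p = 0.80). Without vehicle replicate 1 the list passed with a median of 0.37. The call was also lost without a filter (0.079) and with equal sums outside small RNA genes (0.070).

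Part of the regulatory T cell (Treg) genes fell. Folr4, the gene of folate receptor 4 (chromosome 9, 14885814 to 14903949), went from 87.1 ± 18.9 to 32.6 ± 4.89 FPKM (SD, n = 3 each; adjusted p = 0.013), and its neighbour Gpr83 (chromosome 9, 14860210 to 14870789) from 15.2 ± 3.70 to 5.30 ± 0.782 FPKM (adjusted p = 0.017). Ctla4, for an inhibitory receptor, dropped from 587 ± 30.2 to 389 ± 27.9 FPKM, and Il2ra, the high-affinity IL-2 receptor chain gene, from 402 ± 45.5 to 257 ± 25.4 FPKM. Ctla4 and Il2ra are also in the T cell activation list, so their falls are not particular to Treg genes. Folr4 kept its call without each library in turn. Ctla4 lost it without any single library (adjusted p between 0.0505 and 0.102). Gpr83 lost it without vehicle replicates 2 or 3 or 2DG replicates 1 or 2 (highest adjusted p = 0.065), and Il2ra without any single library but vehicle replicate 1 (highest adjusted p = 0.14). Foxp3, the lineage factor of Treg cells, shared its locus with 4930524L23Rik, and this shared locus was at 8.81 ± 6.07 FPKM with vehicle and 5.24 ± 1.66 FPKM with 2DG, which did not differ beyond its error (adjusted p = 0.72). Of 20 tested members 4 fell, 0 rose and 16 did not pass, and adjusted over the list alone 8 were lower and 2 higher. The list was called lower (median -0.50, camera adjusted p = 0.0035; adjusted p = 0.52 with an estimated correlation). It was -0.32 without vehicle replicate 2 and -0.30 with relative depth as a covariate, where the list passed (adjusted p = 0.019 and 0.018). Its medians were -0.24 in the replicate 1 libraries and -0.45 in replicates 2 and 3. The Th2 list, with 6 tested members, was called lower (median -0.45, adjusted p = 0.0036; adjusted p = 0.43 with an estimated correlation), although Il24 was its only member past the test and 2 were lower adjusted over the list alone. Its medians were -0.44 in the replicate 1 libraries and -0.61 in replicates 2 and 3. With replicates 2 and 3 only, where the filter was applied to those libraries alone, the Th2 median was -0.46. Il4ra, a receptor chain for IL-4, was at 161 and 96.9 FPKM (adjusted p = 0.086). The Th2 call was lost without a filter on low values (median -0.01, adjusted p = 0.25), and its median was -0.27 without vehicle replicate 2 and -0.25 with relative depth as a covariate.

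Genes that mark T cell activation split, with 5 of 24 higher and 3 lower, and 10 higher and 6 lower adjusted over the list alone. Pdcd1, which encodes PD-1, rose from 37.0 ± 7.79 to 96.6 ± 14.8 FPKM (SD, n = 3 each; adjusted p = 0.016), and Spry1, an inhibitor of receptor tyrosine kinase signalling, by 1.20 ± 0.10 on the log2 scale (SE, adjusted p = 0.0034). Cd40lg, Cd69 and Egr3 also rose and were named after their values were seen. Dusp5, for a phosphatase that acts on ERK, fell by 1.36 ± 0.18 (SE, adjusted p = 0.016), as did Ctla4 and Il2ra. Without 2DG replicate 1 or 2DG replicate 2, Pdcd1 and Dusp5 lost their calls (highest adjusted p = 0.063 for each). The list as a whole was not called (median 0.13, camera adjusted p = 0.32). In the naive and quiescent T cell list 2 of 20 fell, Ly6c1 and the lymph node homing receptor Ccr7, and 0 rose. Ly6c1 lost its call without vehicle replicate 1, vehicle replicate 2 or 2DG replicate 2 (highest adjusted p = 0.071), and Ccr7 without any single library but vehicle replicate 3 (highest 0.17). In this list 3 were higher and 4 lower adjusted over the list alone. Its median was 0.07 while its mean was -0.11 and the test pointed down (adjusted p = 0.93). In the interferon response list 1 of 12 rose and 0 fell, with 2 higher and 5 lower adjusted over the list alone (median -0.12, adjusted p = 0.43). The interferon median was -0.04 without a filter and with a minimum mean of 5 FPKM, and ran from -0.17 to -0.06 with 1 library left out. It was -0.07 with replicates 2 and 3 only, where the filter was applied to those libraries alone. Medians in the replicate 1 libraries and in replicates 2 and 3 were 0.09 and 0.09 for activation, 0.12 and 0.01 for the naive list and -0.12 and -0.13 for interferon.

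Several ER chaperone genes rose. Hspa5, which encodes the chaperone BiP, went from 365 ± 29.3 to 668 ± 75.1 FPKM (SD, n = 3 each; adjusted p = 0.016), and Herpud1, a gene of ER-associated degradation, from 49.7 ± 3.02 to 94.5 ± 7.83 FPKM (adjusted p = 0.0054). Hyou1 and Dnajc3, further ER chaperone genes, rose by 0.67 and 0.55 on the log2 scale (adjusted p = 0.019 and 0.016). The fifth was Creld2 (0.69, adjusted p = 0.021), named after its values were seen. Herpud1 kept its call without each library in turn, whereas Hspa5 lost it without vehicle replicate 2, vehicle replicate 3 or 2DG replicate 1 (highest adjusted p = 0.057). Dnajc3 lost it without 2DG replicate 1 or 2DG replicate 2 (highest 0.070), and Hyou1 without any single library but 2DG replicate 1 (highest 0.070). Of 24 tested members 5 rose, 0 fell and 19 did not pass over all genes, and adjusted over the list alone 16 were higher and 1 lower. The list had the smallest p of the 30 tested (median 0.43, camera adjusted p = 3.02e-11), and its adjusted p with an estimated correlation was 0.28. Its median was 0.34 in the replicate 1 libraries and 0.46 in replicates 2 and 3. In the N-glycosylation and hexosamine list 0 of 32 passed limma's test, over all genes or adjusted over the list alone, while 3 were higher and 3 lower at an unadjusted p under 0.05. Its median was -0.02 and its mean -0.01, although the test pointed up (adjusted p = 0.93), with medians of -0.05 in the replicate 1 libraries and 0.03 in replicates 2 and 3. Fry's test for change in either direction gave the list an adjusted p of 4.4e-05, so members may move both ways. That test makes no comparison with other genes, and the interferon response list had the same value. Most of the tested lists passed it, among them lists without a called gene such as fatty acid oxidation (fry adjusted p = 0.012) and pentose phosphate (0.044). Passing it therefore does not set the N-glycosylation list apart.

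Several genes of amino acid supply also rose. Slc7a3, a cationic amino acid transporter gene (XLOC_022916, chromosome X, 101079210 to 101086020), went from 3.63 ± 0.438 to 20.2 ± 3.35 FPKM (SD, n = 3 each; adjusted p = 0.0016) and Slc1a4, a neutral amino acid transporter gene, from 6.81 ± 0.378 to 15.6 ± 1.85 FPKM (adjusted p = 0.0054). Of 10 tested amino acid transporters 3 rose, the third being the glycine transporter gene Slc6a9, 0 fell, and 6 were higher and 0 lower adjusted over the list alone. All 10 fold changes were positive (median 0.29, camera adjusted p = 1.55e-07; adjusted p = 0.35 with an estimated correlation). Among 23 tested ATF4 target genes Stc2 and Asns, the asparagine synthetase gene, rose and 0 fell. Asns went from 54.6 ± 11.7 to 121 ± 13.4 FPKM (adjusted p = 0.017), while Atf3, a transcription factor gene of the same list, was at 5.42 ± 2.02 and 1.70 ± 0.376 FPKM (adjusted p = 0.053; 0.031 without vehicle replicate 3). Adjusted over the list alone 9 were higher and 1 lower, and the list was called higher (median 0.35, adjusted p = 7.42e-07; adjusted p = 0.35 with an estimated correlation). Cth, for the enzyme that makes cysteine from cystathionine (XLOC_013633, chromosome 3, 157894248 to 157925077), rose from 5.14 ± 0.615 to 24.4 ± 4.94 FPKM (adjusted p = 0.0032). In the serine and one-carbon list Mthfd2 and Aldh1l2, both mitochondrial folate enzyme genes, rose, 0 of 14 fell, and 6 were higher and 0 lower adjusted over the list alone (median 0.19, adjusted p = 0.0015; adjusted p = 0.28 with an estimated correlation). Medians in the replicate 1 libraries and in replicates 2 and 3 were 0.36 and 0.31 for the transporters, 0.17 and 0.34 for the ATF4 targets and 0.19 and 0.21 for the serine list. Slc7a3, Slc1a4 and Cth kept their calls without each library in turn, and Slc1a4 lost it with replicates 2 and 3 only (adjusted p = 0.060). Asns lost it without vehicle replicates 2 or 3 or 2DG replicate 2 (highest adjusted p = 0.065) and Stc2 without vehicle replicate 2 (0.054). Slc6a9 kept it without 2DG replicate 3 only (highest 0.13), Mthfd2 without vehicle replicate 1 only (highest 0.073) and Aldh1l2 without 2DG replicate 1 only (highest 0.12).

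Transcripts of glycolysis, the pathway that 2DG is used to inhibit, did not pass the test. None of the 22 tested members was called by limma, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05, 2 were higher and 0 lower. Hexokinase 2 (Hk2) was at 60.9 ± 6.21 and 55.6 ± 10.8 FPKM, lactate dehydrogenase A (Ldha) at 1376 ± 91.0 and 1341 ± 146 FPKM and the glucose transporter gene Slc2a1 at 141 ± 14.2 and 151 ± 25.9 FPKM (SD, n = 3 each; adjusted p = 0.68, 0.90 and 0.77). Gapdh was listed at 0.135 to 1.12 FPKM in every library although cells use it throughout, so its values were not read. The list median was 0.09 (camera adjusted p = 0.13), but it was -0.23 in the replicate 1 libraries and 0.20 in replicates 2 and 3. The relation thus did not hold across these sets of libraries. The list was called higher without 2DG replicate 1 (adjusted p = 3.2e-04) and without vehicle replicate 2 (adjusted p = 0.023). It was also called higher with replicates 2 and 3 only (adjusted p = 1.5e-04) and with relative depth as a covariate (median 0.17, adjusted p = 0.0090). Without vehicle replicate 3 the median was 0.01, without 2DG replicate 3 it was 0.05 and without 2DG replicate 2 it was -0.02. HIF-1 targets outside glycolysis behaved alike, with a median of 0.12 (adjusted p = 0.083), -0.13 in the replicate 1 libraries and 0.25 in replicates 2 and 3, and a call without 2DG replicate 1 (adjusted p = 0.0015) or vehicle replicate 2 (adjusted p = 0.019). They were also called with replicates 2 and 3 only (adjusted p = 0.0046) and with relative depth as a covariate (median 0.22, adjusted p = 0.0071). Their median ran from 0.07 to 0.28 with 1 library left out and was 0.07 after the GC and length correction. Among the 20 tested members Rnf19a rose (lost without vehicle replicates 1 or 3 or 2DG replicates 1 or 2, highest adjusted p = 0.077) and the prolyl hydroxylase gene Egln3 fell, by 0.71 ± 0.13 on the log2 scale (SE, adjusted p = 0.039; between 0.053 and 0.12 without any single library), and 2 were higher and 2 lower adjusted over the list alone. Hif1a was at 307 ± 61.7 and 239 ± 45.1 FPKM (adjusted p = 0.36), Myc at 57.2 ± 8.40 and 55.8 ± 7.91 FPKM (adjusted p = 0.93) and Txnip, a glucose-responsive arrestin gene, at 23.9 ± 5.32 and 37.3 ± 6.48 FPKM (adjusted p = 0.12). The list of Txnip and related glucose-sensing genes had 0 of 6 past limma's test over all genes, 3 higher and 0 lower adjusted over the list alone, 3 higher and 0 lower at an unadjusted p under 0.05, and a median of 0.23 (adjusted p = 0.15), which was 0.04 in the replicate 1 libraries and 0.27 in replicates 2 and 3. With replicates 2 and 3 only, where Arrdc4 no longer reached the minimum mean, it was 0.05, and after rescaling to an equal sum it was -0.01.

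**Figure D2:**
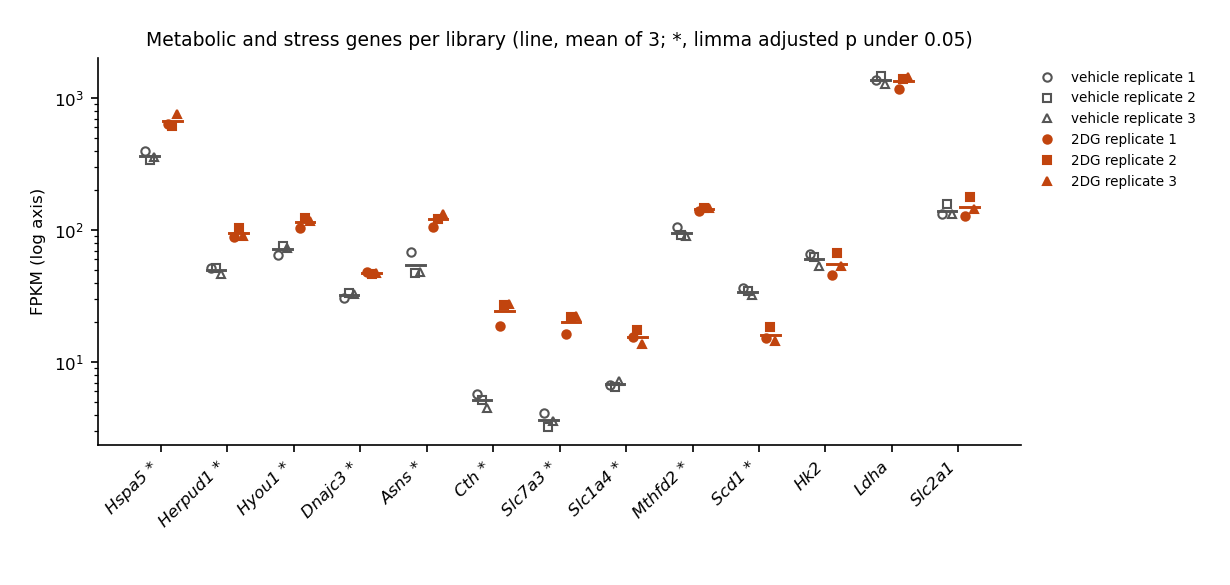
FPKM (log axis) of 13 metabolic and stress genes in each of the 3 vehicle libraries (open grey symbols) and 3 2DG libraries (filled orange symbols), with symbol shapes for replicates 1 to 3, lines for group means and an asterisk for a limma adjusted p under 0.05. Hspa5, Asns, Slc7a3 and Slc1a4 lie higher with 2DG, Scd1 lies lower, and Hk2, Ldha and Slc2a1 overlap between groups.

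Some lipid synthesis genes fell. Scd1, for stearoyl-CoA desaturase, dropped from 34.2 ± 2.09 to 16.0 ± 2.15 FPKM (SD, n = 3 each; adjusted p = 0.0065). It kept its call without each library in turn and lost it with replicates 2 and 3 only (adjusted p = 0.064). Fads2 and Elovl6, which desaturate and elongate fatty acids, fell by 0.57 and 0.53 on the log2 scale (adjusted p = 0.031 and 0.046), and Fads2 lost its call without any single library (adjusted p between 0.062 and 0.099). Elovl6 lost it without any single library but 2DG replicate 3 (highest adjusted p = 0.17). Of 13 tested fatty acid synthesis genes 3 fell and 0 rose, and 5 were lower and 0 higher adjusted over the list alone (median -0.16, camera adjusted p = 0.0017; adjusted p = 0.35 with an estimated correlation). The median was -0.07 without 2DG replicate 1, -0.25 without 2DG replicate 2, -0.08 with relative depth as a covariate and -0.09 after the GC and length correction, and the list passed in each case. Lysosome and autophagy genes were called lower as a list (median -0.18, adjusted p = 0.0015; adjusted p = 0.52 with an estimated correlation). Gabarapl1, an autophagosome protein gene, and Gla, the alpha-galactosidase gene, were the 2 of 25 that fell, with 0 that rose and 2 lower and 0 higher adjusted over the list alone. The medians were -0.29 in the replicate 1 libraries and -0.11 in replicates 2 and 3 for fatty acid synthesis, and -0.03 and -0.20 for the lysosome list. Without vehicle replicate 2 the lysosome median was -0.12 and the list passed. Gabarapl1 lost its call without vehicle replicates 2 or 3 or 2DG replicates 1 or 2 (highest adjusted p = 0.080), and Gla without any single library but 2DG replicate 3 (highest 0.099).

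Further metabolic lists were called lower with small medians. In the TCA cycle list 1 of 22 fell and 0 rose, with 1 lower and 0 higher adjusted over the list alone (median -0.08, camera adjusted p = 0.023; adjusted p = 0.52 with an estimated correlation). For 57 nuclear-encoded subunits of oxidative phosphorylation the median was -0.08 (adjusted p = 0.0072; adjusted p = 0.62 with an estimated correlation), for 23 cholesterol genes -0.08 (adjusted p = 0.023; adjusted p = 0.52 with an estimated correlation) and for 15 NRF2 targets -0.15 (adjusted p = 0.023; adjusted p = 0.35 with an estimated correlation). No member of these 3 lists passed limma's test over all genes, and adjusted over the list alone 1 cholesterol gene was lower and 0 of the others were called. At an unadjusted p under 0.05, 1 was higher and 6 lower for oxidative phosphorylation, and 0 higher and 6 and 4 lower for cholesterol and NRF2. All of these calls depended on single libraries and on the processing. Without vehicle replicate 1 the adjusted p was 0.17 for the TCA cycle, 0.15 for oxidative phosphorylation, 0.20 for cholesterol and 0.052 for NRF2. The TCA list was also lost without 2DG replicate 1 (0.055) or 2DG replicate 2 (0.088), the oxidative phosphorylation list without 2DG replicate 2 (0.079), the cholesterol list without 2DG replicate 3 (0.22) and the NRF2 list without vehicle replicate 2 (0.085). Their medians were -0.17, -0.20, -0.11 and -0.20 in the replicate 1 libraries and -0.04, -0.04, -0.09 and -0.11 in replicates 2 and 3, in the same order. With 1 library left out the TCA median was -0.05 without vehicle replicate 1 and -0.14 without 2DG replicate 3, and that of oxidative phosphorylation -0.05 without 2DG replicate 1 and -0.13 without vehicle replicate 3. The cholesterol median was -0.02 without vehicle replicate 1 and without 2DG replicate 3, and the NRF2 median -0.10 without 2DG replicate 2. After rescaling to an equal sum the adjusted p was 0.060, 0.071, 0.084 and 0.14 for the TCA, oxidative phosphorylation, cholesterol and NRF2 lists, and with replicates 2 and 3 only 0.32, 0.44, 0.055 and 0.079. With equal sums outside small RNA genes the TCA and NRF2 calls were lost (0.054 and 0.052), and the medians of the other lists were -0.03 for oxidative phosphorylation and -0.02 for cholesterol. The oxidative phosphorylation call was also lost with quantile normalization (0.11) and the GC and length correction (0.0504), and the NRF2 call with quantile normalization (0.054) and without a filter (0.079).

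Lists of proliferation and housekeeping did not pass. The median was -0.05 for 38 cell cycle genes (camera adjusted p = 0.085), 0.05 for 36 MYC target and ribosome biogenesis genes (adjusted p = 0.085), -0.09 for 16 fatty acid oxidation genes (adjusted p = 0.086), -0.02 for 10 pentose phosphate genes (adjusted p = 0.87), 0.06 for 11 cytosolic heat shock genes (adjusted p = 0.62) and -0.03 for 14 CD4 T cell identity genes (adjusted p = 0.87). In these 6 lists limma called no gene over all genes, and adjusted over the list alone 1 CD4 identity gene was lower. At an unadjusted p under 0.05, counts higher and lower were 0 and 1 for cell cycle, 2 and 0 for MYC, 1 and 4 for fatty acid oxidation, 1 and 1 for pentose phosphate, 1 and 0 for heat shock and 0 and 1 for CD4 identity. Medians in the replicate 1 libraries and in replicates 2 and 3 were -0.04 and -0.05, 0.12 and 0.04, -0.20 and -0.05, 0.02 and -0.03, 0.12 and -0.02, and -0.08 and 0.03, in the same order. The cell cycle and fatty acid oxidation lists were called lower without 2DG replicate 3 (adjusted p = 0.017 and 0.019), and the fatty acid oxidation and MYC lists were called, lower and higher, without vehicle replicate 3 (0.024 and 0.015). The MYC list was also called with quantile normalization (0.025) and the GC and length correction (0.041), and the cell cycle list without a filter and with that correction (0.041 each). With 1 library left out the median ran from -0.09 to -0.03 for cell cycle and from 0.04 to 0.08 for MYC. It ran from -0.15 to -0.05 for fatty acid oxidation and from -0.01 to 0.05 for heat shock. With equal sums outside small RNA genes the cell cycle median was 0.0014. In the p53 list 1 of 17 rose, the kinase gene Plk2, from 8.22 ± 0.717 to 21.8 ± 2.96 FPKM (SD, n = 3 each; limma adjusted p = 0.0040), 0 fell, 2 were higher and 0 lower adjusted over the list alone, and the list did not pass (median 0.03, adjusted p = 0.46; 0.06 in the replicate 1 libraries and -0.06 in replicates 2 and 3). The locus that names both the heat shock gene Dnaja1 and the short RNA gene Mir207 was listed at 9.02 to 9.19 FPKM in the vehicle libraries and at 241, 8.70 and 272 FPKM in the 2DG libraries (adjusted p = 0.23). It was called higher without 2DG replicate 2 (adjusted p = 9.2e-06), but the table gives 1 value for both genes, so it is not known whether the values are those of Dnaja1.

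**Figure D3:**
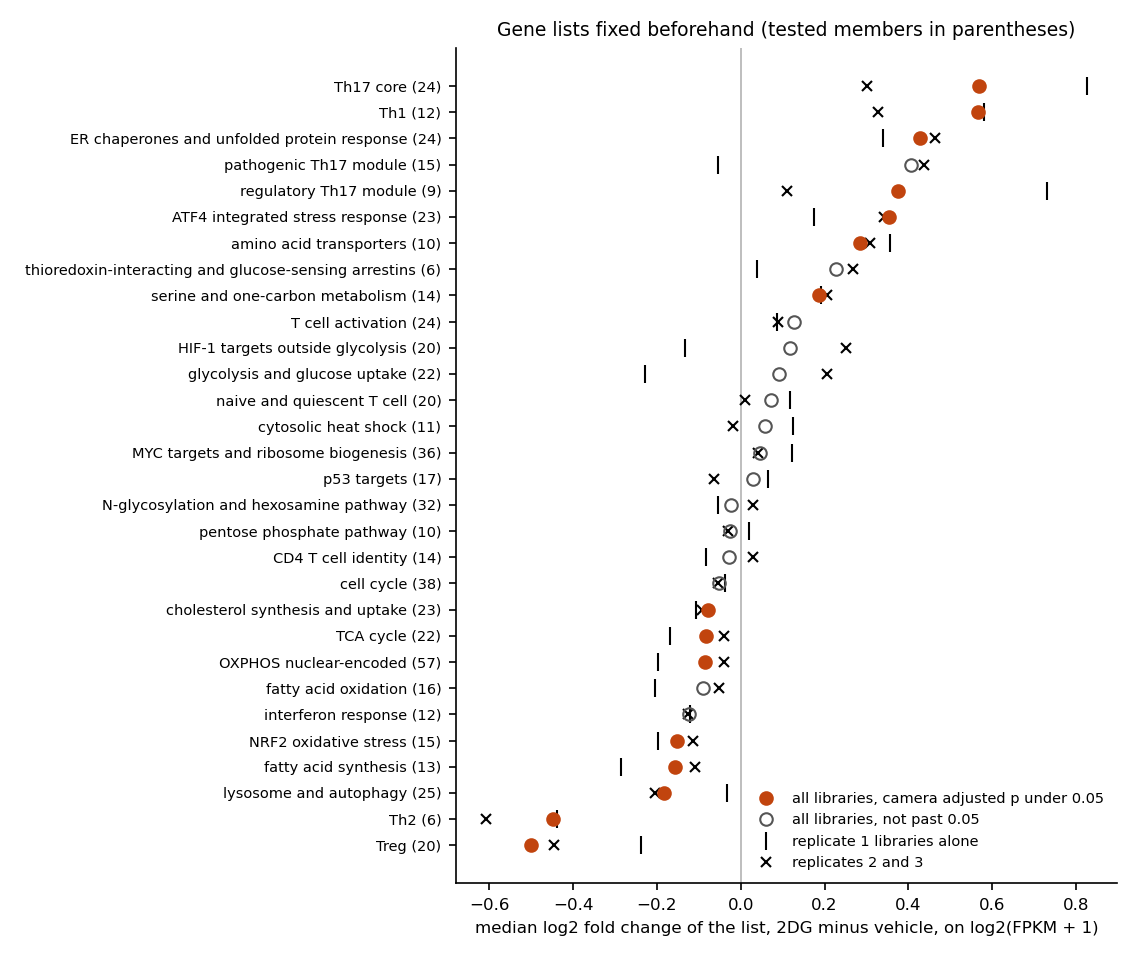
Median log2 fold change (2DG minus vehicle, on log2(FPKM + 1)) of each of the 30 tested gene lists, with the number of tested members in parentheses; filled orange circles passed camera at an adjusted p under 0.05 and open grey circles did not, bars mark the replicate 1 libraries alone and crosses replicates 2 and 3. The Th17 core list has a median of 0.57 and the Treg list one of -0.50, while bar and cross of the glycolysis list lie on opposite sides of 0.

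Over the 30 lists, 7 were called higher and 8 lower by camera with a preset correlation of 0.01, and 0 with an estimated correlation (smallest adjusted p = 0.28). With fry, which tests whether a list's genes move one way without comparing them with other genes, 5 lists passed: the ER chaperone, serine and one-carbon, amino acid transporter and Th1 lists as higher and the fatty acid synthesis list as lower. Without vehicle replicate 1, 4 lists were called lower, in place of 8.

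Markers of other cell types ranged from near 0 to 85.5 FPKM. Among the low ones, chosen after their values were seen, Itgam of myeloid cells was at 0.0230 FPKM with vehicle and 0.0873 FPKM with 2DG, Cd8a of CD8 T cells at 0.0612 and 0.280 FPKM and Ncr1 of NK cells at 0.0252 and 0 FPKM. Too few members passed the filter for a list test: 4 of the B cell, 4 of the myeloid, 4 of the CD8 T cell, 1 of the NK and gamma-delta and 0 of the erythroid markers. Among the tested ones H2-Ab1 (22.3 and 32.4 FPKM), Cst3 (85.5 and 67.2 FPKM) and Klrd1 (26.8 and 13.4 FPKM) were the highest of their lists and did not differ by the test (adjusted p = 0.43, 0.30 and 0.30), and Crtam, a member of the CD8 T cell list, was the only one that passed. None of the 13 mitochondrially encoded transcripts of the fixed list was matched to a locus of the table by name.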

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

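The settings without small RNA genes, with equal sums outside them, with status OK loci, with the batch term for replicate 1, with replicates 2 and 3 only, with relative depth as a covariate and with GC content and length corrected were chosen after the data were seen. The 2 alternatives meant for counts were not run, since the values are FPKM.

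Against 156 higher and 122 lower genes, there were 100 and 65 with no filter, where 15371 loci were tested, 87 and 63 after rescaling to an equal sum, 247 and 199 with robust eBayes, 265 and 224 without small RNA genes and 43 and 28 with replicates 2 and 3 only. Lower genes were 80 with the batch term and 191 after the GC and length correction. Leaving out 1 library gave 52 to 98 higher and 25 to 69 lower genes, from fewer samples. Apart from the replicate block, given separately, other settings stayed within 1.5 times. Every called gene that was tested kept its sign in each setting, which groups that do not overlap fix in advance where libraries are only left out. Of the calls, 127 kept their call after rescaling, 146 with no filter, 178 with the batch term and 55 with replicates 2 and 3 only. Apart from the filter and the numbers of samples, the cause was not tested.

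With a replicate block there were 57 and 44 genes, and 91 calls were kept. Of 53 called genes among those named by rule, 28 lost their call under this block. The deviations of same-numbered libraries from their group means correlated by -0.0506, 0.193 and -0.112 across genes, which are not independent replicates, and vehicle replicate 2 alone correlated best with its own number, which does not show that the numbers pair the samples. Same-numbered libraries did share technical traits: Rn45s was above 0 in the replicate 1 libraries alone, and Lars2 and relative depth ranked replicates 1 to 3 alike in both groups. A shared batch per number therefore stays open.

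Against 7 higher and 8 lower lists, there were 0 and 0 with an estimated correlation, and 4 and 1 with fry. Lower lists were 4 after rescaling to an equal sum, 4 with replicates 2 and 3 only and 4 to 9 with 1 library left out.

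No called gene changed sign, and no called list changed the direction of its test, but the median of the called Th1 list was -0.40 with a minimum mean of 5, where fewer genes are tested and the list was not called. Among results that were not called, with relative depth as a covariate the value was 0.0317 for the pentose phosphate list, -0.00412 for N-glycosylation (whose test then pointed down), 0.0521 for CD4 identity, 0.0552 for the Foxp3 locus, 0.0102 for Ldha and 0.0819 for Myc. The N-glycosylation median was -0.0238 with no filter, the replicate block, fry and the batch term, and -0.0113 after rescaling, with the test pointing down. The CD4 identity median was -0.00550 after quantile normalization, 0.0298 with replicates 2 and 3 only and 0.00422 after the GC and length correction, with the test pointing up. With replicates 2 and 3 only Hk2 was at 0.0419 and Ldha at 0.0491, and with equal sums outside small RNA genes Ldha was at 0.0139 and Myc at 0.0206. With 1 library left out the range was -0.0830 to 0.0126 for pentose phosphate, -0.0475 to 0.0169 for N-glycosylation, 0.0195 to 0.116 for the naive list, -0.0684 to 0.0592 for CD4 identity, -1.06 to 0.0187 for the Foxp3 locus, -0.0999 to 0.0515 for Ldha, -0.0374 to 0.199 for Slc2a1 and -0.159 to 0.0622 for Myc. The cause was not tested.

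Depth limits low genes most, and without counts that limit has no number here.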

Other observations

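Of the tests below, those of library depth and of the share of Treg-like cells were written after related values had been seen; the others were written before their result. The margin of 1 SE in the depth and GC comparisons was added afterwards.

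Among 157 groups of at least 8 tested genes with the same symbol stem, a search made after seeing the data, those of Hist (histone genes) and Gimap (GTPases of lymphocytes) passed camera at a preset correlation. The 157 include 16 genes grouped under an empty stem. The 56 histone genes had a median log2 fold change of -0.18 (adjusted p = 8.1e-04) with 0 genes past the test by limma, and the 8 Gimap genes one of -0.34 (adjusted p = 0.026) with 1 lower. With an estimated correlation the adjusted p was 0.94 for both.

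The real split of the 6 libraries called 278 genes, and the highest of the other splits 4; 1 of the 10 splits, the real one, gave as many. For lists it was 15 against 11 (vehicle replicates 1 and 2 with 2DG replicate 1), again with 1 of 10 splits as large. As 3 against 3 libraries make only 10 splits, a share under 0.05 cannot be reached. Each other split also mixes both treatments in each group, so a difference between treatments adds to its spread and lowers its gene count. The gap between 278 and 4 is thus partly fixed in advance. Over the 9 other splits, a permutation of the libraries, the ER chaperone list had a camera p of 1.01e-12 in the real split and at least 5.14e-06 otherwise, the Treg list 9.41e-04 against 0.0031, the glycolysis list 0.089 against 6.6e-15, and the oxidative phosphorylation list 0.0024 against 6.28e-10. Of the called lists, those of cholesterol (0.0106 against 7.35e-06), regulatory Th17 genes (0.0073 against 1.57e-05) and the TCA cycle (0.0115 against 5.3e-04) also had a smaller p in some other split. These 5 lists thus separated some other splits of the libraries more than the groups. For the ATF4 list the camera p was 7.42e-08 in the real split and at least 4.53e-07 otherwise. It was 1.04e-08 against 6.52e-06 for the amino acid transporters and 6.25e-07 against 2.27e-05 for the Th17 core list. Splits that mix the treatments thus also gave these lists small values, though none as small as the real split.

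The first pattern is the rise of the ER chaperone list. After trends with GC content and transcript length were removed from each library, its median was 0.4494 ± 0.061 (SE over members) in place of 0.4288, and the list still passed, which argues against those trends as the whole cause. With relative depth as a covariate the median was 0.4357 ± 0.066 and the list passed, which argues in the same way against depth as far as the rough estimates measure it. Between the shallower 2DG replicate 2 and vehicle replicate 1 it was 0.37; the covariate replaced this comparison, written first, because a single pair excludes nothing. Both SEs are taken over member genes of the same 6 libraries, so they do not measure the spread between libraries. The list passed at the preset correlation. With an estimated correlation, in the main fit, its camera adjusted p was 0.28. How 2DG itself would raise these genes was not tested.

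The second pattern is the fall of the Treg list. Its median was -0.4799 ± 0.16 after the GC and length correction, against -0.50 without it, which argues against those trends as the whole cause. With relative depth as a covariate it was -0.2998 ± 0.16 (SE over members), against -0.5012 without it. This error does not measure the spread between libraries, and it already reaches values at which depth would account for most of the fall. Between 2DG replicate 2 and vehicle replicate 1 the median was -0.07, but this single pair decides nothing, as it also crosses replicate numbers. From the covariate fit, depth and 2DG cannot be told apart for this list with depth estimates this rough. A smaller share of Treg-like cells may contribute, but the locus of Foxp3 had a log2 fold change of -0.4394 ± 0.52 (SE), whose interval holds both 0 and the median of the list, and so leaves this open.

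Another pattern starts from the fall of Il2ra: lower IL-2 receptor signalling in 2DG would let targets of STAT5, the transcription factor it activates, fall together. Of 16 STAT5 targets written down before the test, Il2rb is in the Treg list and was left out, as the prediction asked, only after a first run that included it. Over the 14 others that were tested, 11 fold changes were negative, the median was -0.36, and Socs1 alone was called lower. The camera p was 1.77e-05, past the written threshold, but with an estimated correlation it was 0.14 and another split of the libraries gave 3.88e-05; with Il2rb the p was 2.43e-05 and another split gave 2.08e-05. A requirement that the estimated correlation also pass was added after these values were seen, and under it the hypothesis stays open.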
